A study of Mus musculus with 16 samples.

How the data were processed

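PolyA RNA of 16 mouse pre-B cell samples was measured by RNA-seq. Per the labels' protocols, 150 ng of RNA per sample entered the Illumina TruSeq Stranded mRNA kit, and both ends of each fragment were read for 100 cycles on a HiSeq instrument. The labels place the samples in 4 groups of 4, which cross the BCR-ABL1 fusion kinase (present or absent) with SHP2, the phosphatase encoded by Ptpn11 (wild type or null). The labels do not say whether the 4 samples of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

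The authors deposited FPKM values (fragments per kilobase of transcript scaled to the mapped fragments of the library), 1 column per library, with genes given by symbol only. Bowtie and Cufflinks and the mouse build mm10 (GRCm38) are named per the submitters' processing notes. Their versions, the annotation, the handling of strand and of multiply mapped reads, and any scaling across libraries are not given in the sources used here. The series table held 23758 entries for 23279 symbols, and the values of 254 symbols listed more than once (733 entries) were summed. The 16 per-library files held the same values as the series table in 16 of 16 libraries.

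FPKM values hold no counts, so the absolute depth of each library is unknown. Relative depth was estimated from genes listed below 0.05 FPKM, taking the commonest ratio of their values between each pair of libraries. That ratio held, within 1%, for 9.51% to 18.8% of 1355 to 1665 genes per pair, too few to recover whole reads. Estimated relative depth ran from 0.795 to 1.27 times the mean, a ratio of 1.60. Summed FPKM ran from 348923 to 443702, and 9829 to 10134 genes reached 1 FPKM in a library. The noncoding RNAs Rpph1 and Rmrp, which are not polyadenylated, ran from 1193 to 16292 and from 1166 to 7869 FPKM.

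Genes with at least 1 FPKM in at least 4 of the 16 libraries were tested (10210 genes). Values were analysed as log2(FPKM + 1), which understates the change of low genes. Every fold change is on that scale. A single limma fit with 4 group means and a trended prior variance gave the 5 comparisons, which were SHP2 loss with BCR-ABL1, SHP2 loss without it, the difference between these effects (the interaction), BCR-ABL1 in SHP2 wild-type cells and BCR-ABL1 in SHP2-null cells. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested, and an adjusted p below 0.05 counted as a call. The software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

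Before the data were examined, the groups, the tests, the alternatives not marked as added, the rule for named genes and 23 gene lists were fixed. The lists were ERK pathway response, the MYC MAX MXD network, MYC targets and ribosome biogenesis, DNA replication and E2F targets, mitosis, cell cycle inhibitors and FOXO targets, STAT5 targets, SRC family kinases and regulators, SHP2 and RAS-ERK pathway members, pre-BCR signalling, early B lineage, mature or activated B cell, p53 targets, BCL2 family, interferon response, cholesterol synthesis, glycolysis, heat shock, replication histones, and markers of myeloid, T and NK, erythroid and megakaryocyte, and stromal cells. With at least 3 measured members asked of each, 21 lists were tested. Each was compared with all other genes by camera in limma with a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry, which asks whether members move one way on balance and makes no comparison with other genes, were run beside it. Of the 27 list calls with the preset correlation, 2 held with an estimated correlation, namely cell cycle inhibitors and FOXO targets in SHP2 loss with BCR-ABL1 and ERK pathway response in BCR-ABL1 with SHP2.

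Named genes followed a rule. Ptpn11, Abl1, Bcr, Mxd3, Mxd4, Myc and Dusp6 were always named. In each comparison the rule added the 10 called genes with the largest rise and the 10 with the largest fall whose 4 libraries of one group all lay above the 4 of the other, without predicted, RIKEN and V, D or J segment genes, small RNAs and similar symbols, and up to 4 members of each list with the smallest p. For the interaction it asked instead for the 10 smallest adjusted p in each direction among calls. The rule allowed genes to be left out for length. Which ones were given was decided after their values were seen. Single libraries far from their group were looked for in 93 genes, also chosen after values were seen. Genes outside the rule are marked where they appear.

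Whether the replicate numbers 0 to 3 pair libraries was read from the data, because the protocol says that libraries were loaded in sets with 1 of each group but not that the number marks the set. Deviations from the group means correlated at 0.22 to 0.78 between same-number libraries for SHP2 loss with BCR-ABL1, at 0.19 to 0.51 for SHP2 loss without it and at 0.24 to 0.68 for BCR-ABL1 without SHP2, all above the limit of 0.1 set for pairing. Fits with the replicate number as a block are therefore given beside those 3 comparisons where they change a call or a count by over 1.5 times. With BCR-ABL1, however, wild-type replicate 2 correlated more with null replicate 3 (0.822) than with null replicate 2 (0.338). Wild-type replicate 3 correlated more with null replicate 2 (0.478) than with null replicate 3 (0.218). Without BCR-ABL1, wild-type replicate 2 correlated more with null replicate 3 (0.538) than with null replicate 2 (0.189). Null replicate 2 with BCR-ABL1 correlated more with null replicate 3 without it (0.385) than with null replicate 2 without it (0.242). Pairing by number is therefore uncertain in all 3 comparisons, and so are the fits with the block.

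The steps were tested on simulated data with genes changed by known folds in 10210 genes. At 2-fold, 94.0% of the changed genes were recovered for SHP2 loss with BCR-ABL1, 95.5% for SHP2 loss without it, 88.1% for the interaction, 98.5% for BCR-ABL1 with SHP2 and 94.0% for BCR-ABL1 without SHP2, and 13, 13, 6, 20 and 13 unchanged genes were called beside the changed ones. In simulated data with no change 0 genes were called. The simulated noise was drawn independently for each gene and library. It lacked the correlation by replicate number seen in the real libraries, so these rates may not carry over to them. Alternatives tried were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, fits on the groups compared only, the replicate block, array weights, a robust prior variance and leaving out each library in turn. Added after seeing the data were pseudocount 0.1 for the list tests, a GC correction with and without the block, counts outside 2 genome windows, and leaving out 1 library from comparisons it is not part of. Positions and transcript GC content came from GENCODE annotation of GRCm38, matched by symbol for 99.0% and 99.2% of the tested genes. Erythroid and megakaryocyte markers (0 measured members) and stromal markers (2) were too low to test.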

Results

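RNA-seq FPKM values were compared across 16 libraries of mouse pre-B cells, the B-lineage precursors in which BCR-ABL1 drives acute lymphoblastic leukaemia. BCR-ABL1 is a constitutively active fusion of the ABL1 kinase, and SHP2 is a phosphatase that carries receptor signals to RAS and ERK. The 4 groups held 4 libraries each, namely SHP2 wild-type and SHP2-null cells without BCR-ABL1 and the same with BCR-ABL1. The files gave no counts, so the depth behind each value was unknown, and relative depth was estimated to span a ratio of 1.60 between libraries.

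Ptpn11, which encodes SHP2, was lower in every library labelled null than in every library labelled wild type. With BCR-ABL1 it averaged 4.52 ± 1.21 FPKM (SD, n = 4) in null and 17 ± 0.957 FPKM in wild-type cells, so that 26.6% remained. Without BCR-ABL1 it averaged 5.79 ± 2.03 and 16.7 ± 0.647 FPKM, so that 34.5% remained. An exact two-sided permutation test gave p = 0.0286 in each case, the smallest that 4 against 4 libraries allow. Which exons were removed is not given in the sources used here, so the remaining signal does not measure remaining protein. Abl1 averaged 15.3 ± 2.21 FPKM in SHP2 wild-type cells with BCR-ABL1 and 16.2 ± 0.662 FPKM without it, and Bcr averaged 6.88 ± 1.14 and 9.06 ± 1.14 FPKM. Neither gene passed in that comparison (limma adjusted p = 0.722 and 0.115), and gene-level values do not separate fusion transcripts from those of the mouse genes. Neither passed with SHP2 loss, with log2 changes of -0.05 ± 0.10 and -0.12 ± 0.12 (SE) with BCR-ABL1 and 0.13 ± 0.10 and 0.13 ± 0.12 without it.

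**Figure D1:**
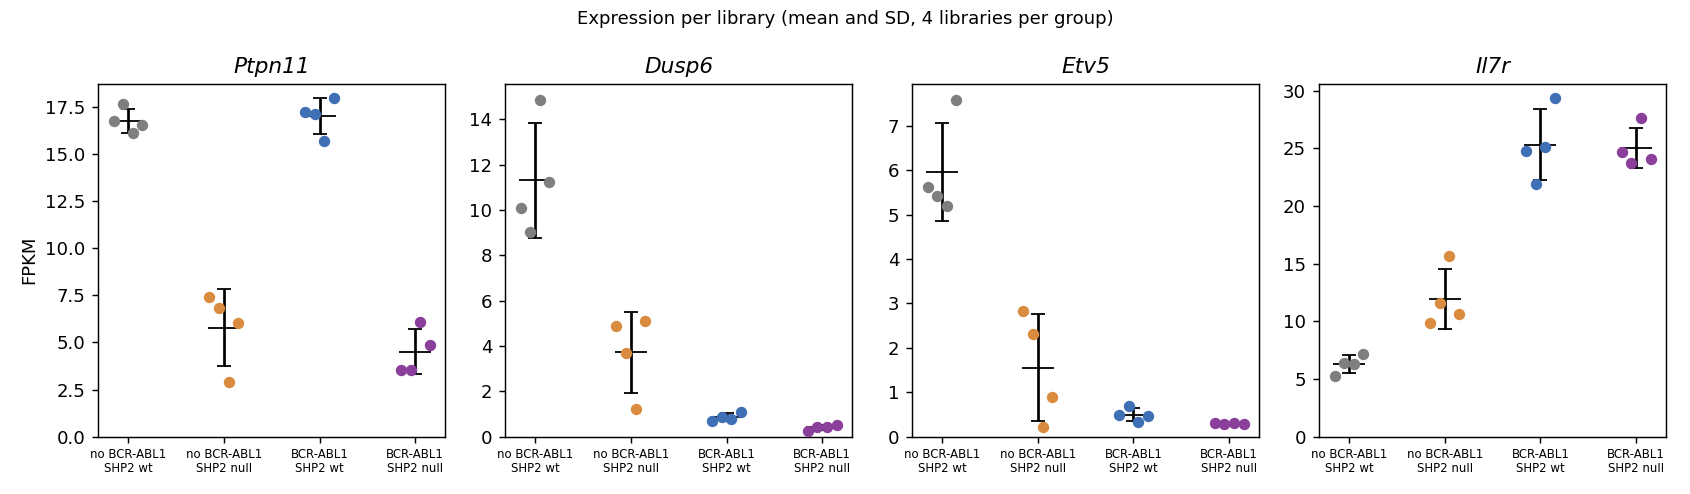
FPKM of Ptpn11, Dusp6, Etv5 and Il7r in each library, by group, with points for libraries and bars for mean and SD (n = 4). Mean Dusp6 and Etv5 were highest, and mean Il7r lowest, in SHP2 wild-type cells without BCR-ABL1, where they averaged 11.3, 5.95 and 6.29 FPKM.

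The first comparison asked what loss of SHP2 changes in cells that carry BCR-ABL1. The small heat shock protein gene Hspb8 fell from 6.67 ± 2.75 to 0.0469 ± 0.0316 FPKM (SD, n = 4), a log2 change of -2.80 ± 0.27 (SE, limma adjusted p = 4.69e-05). Mid1, a ubiquitin ligase gene, fell from 2.52 ± 0.652 to 0.653 ± 0.310 FPKM, and Pop5, which encodes a subunit of RNase P and RNase MRP, fell from 21 ± 0.370 to 14.3 ± 1.37 FPKM. Grina rose from 3.25 ± 0.176 to 6.96 ± 0.474 FPKM, and Nnt, which encodes a mitochondrial transhydrogenase, rose from 17.2 ± 0.742 to 23.6 ± 1.15 FPKM. The zinc finger gene Zfp605 rose from 2.55 ± 0.295 to 4.93 ± 0.367 FPKM, while Zfp213 fell from 4.77 ± 0.805 to 2.24 ± 0.327 FPKM. The calcium channel gene Cacna1h read 0.907 to 1.25 FPKM in the 4 wild-type libraries and was listed at 0 in 3 null libraries and at 0.002353 FPKM in the other. Dcpp2, of a gene family whose copies may share reads, is uncertain and was listed at 0 in all 4 wild-type libraries and at 0.776 to 1.76 FPKM in the null libraries.

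In all, 32 of 10210 genes changed with loss of SHP2 in cells with BCR-ABL1 (18 higher, 14 lower, 7 of them by at least 2-fold, or 16 with pseudocount 0.1). Over all 10210 genes the 4 libraries of one group lay above the 4 of the other for 316 (3.10%), where chance gives 2.86%. At an unadjusted limma p below 0.05 there were 373 genes, fewer than the 510.5 expected by chance, and 849 with the replicate block. Without wild-type replicate 2 or 3 with BCR-ABL1 the count of changed genes was 21 or 20. Of the 30 called genes with a position other than Ptpn11, 11 lay within 20 Mb of Ptpn11 on chromosome 5 and 11 within 14 to 34 Mb of chromosome 17, and 8 lay elsewhere. These windows were set after the data were seen. Hspb8 (chromosome 5, 116408491 to 116422864, GRCm38), Pop5 (115235836 to 115245351) and Zfp605 (110110092 to 110129794) lay near Ptpn11 (121130533 to 121191397). Cacna1h (chromosome 17, 25374285 to 25433783), Zfp213 (23556767 to 23564238) and Dcpp2 (23880880 to 23900788) lay in the chromosome 17 window, while Mid1 lay on chromosome X (169685199 to 170005736) and Grina on chromosome 15 (76246764 to 76249904).

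Among the fixed lists, cell cycle inhibitors and FOXO targets lay higher in SHP2-null cells with BCR-ABL1. These genes include brakes on the cell cycle and targets of the FOXO transcription factors. Of 21 measured members 18 had a positive change, while 0 passed singly in limma (5 at an unadjusted p below 0.05) and 0 adjusted over the list alone. Cdkn2b averaged 1.33 ± 0.236 in wild-type and 2.01 ± 0.117 FPKM (SD, n = 4) in null cells, Txnip 25 ± 2.40 and 36.1 ± 9.06 FPKM, and Ccng2 28.9 ± 4.59 and 37.8 ± 3.97 FPKM. The list passed in limma's camera test (adjusted p = 3.32e-07), with adjusted p = 0.0163 with an estimated correlation and 0.0574 with that and a replicate block, and did not pass with fry (0.0559). With 1 choice changed at a time its adjusted p ran from 1.12e-07 to 0.0559.

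Other lists in this comparison passed with the preset correlation only, and 0 of their members passed singly in limma or adjusted over the list alone. At an unadjusted p below 0.05 were 7, 3, 0, 1 and 0 members in the order named here. MYC targets and ribosome biogenesis lay lower (39 of 40 members, camera adjusted p = 4.43e-11), as did DNA replication and E2F targets (27 of 29, adjusted p = 9.52e-07) and heat shock (6 of 6, adjusted p = 0.0363, or 0.0547 with the replicate block). Glycolysis lay higher (17 of 17, adjusted p = 2.16e-08), as did cholesterol synthesis (18 of 18, adjusted p = 0.000118). Each had an adjusted p = 0.467 with an estimated correlation. With 1 choice changed at a time, adjusted p ran from 1.1e-12 to 0.467 for MYC targets, 3.28e-08 to 0.467 for E2F targets and 2.24e-16 to 0.689 for glycolysis, whose mean log2 change was 0.37, and 0.22 without null replicate 2 with BCR-ABL1. The heat shock call was lost on leaving out null replicate 1 with BCR-ABL1 (0.184), null replicate 3 with BCR-ABL1 (0.169), wild-type replicate 0 with BCR-ABL1 (0.208) and wild-type replicate 1 with BCR-ABL1 (0.0567). Its mean log2 change was -0.13, and -0.084 without wild-type replicate 0. For heat shock adjusted p ran from 0.00161 to 0.488 with 1 choice changed at a time. The cholesterol call was lost on leaving out wild-type replicate 0 with BCR-ABL1 (0.289). Its mean log2 change was 0.16, with 0.04 without that library and 0.27 without wild-type replicate 1. For cholesterol synthesis adjusted p ran from 6.88e-08 to 0.689 with 1 choice changed at a time. ERK pathway response genes, which report signalling through the ERK kinases, did not pass (0 of 9 singly in limma, 0 at an unadjusted p below 0.05, and 0 adjusted over the list alone, camera adjusted p = 0.272), with Dusp6 at 0.873 ± 0.172 and 0.406 ± 0.106 FPKM (SD, n = 4, limma adjusted p = 1). The ERK genes Dusp6, Etv5 and Spred2 averaged below 1 FPKM with BCR-ABL1, where the log2(FPKM + 1) scale understates changes (-0.41 for Dusp6). A fall of these genes is therefore not ruled out. Myc and its antagonists did not pass, with log2 changes of -0.16 ± 0.19 for Myc, 0.02 ± 0.13 for Mxd3 and 0.13 ± 0.16 for Mxd4 (SE).

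The second comparison asked what loss of SHP2 changes in cells without BCR-ABL1. Dusp6, a phosphatase that switches ERK off, fell from 11.3 ± 2.53 to 3.72 ± 1.79 FPKM (SD, n = 4), a log2 change of -1.46 ± 0.24 (SE, limma adjusted p = 0.00435). The ETS transcription factor gene Etv5 fell from 5.95 ± 1.10 to 1.56 ± 1.21 FPKM, and Spred2 and Spred1, which encode inhibitors of RAS signalling, fell from 2.03 ± 0.401 to 0.854 ± 0.114 and from 14.8 ± 2.14 to 8.91 ± 2.80 FPKM. Of the 9 measured genes of the list 4 fell (5 adjusted over the list alone, or over all genes with the replicate block), with camera adjusted p = 2.01e-05 and adjusted p = 0.107 with an estimated correlation (1.82e-07 to 0.107 with 1 choice changed at a time). The call of Spred1 was lost on leaving out null replicate 2 without BCR-ABL1 (0.0772), null replicate 3 without BCR-ABL1 (0.0790), wild-type replicate 0 without BCR-ABL1 (0.0919), wild-type replicate 1 without BCR-ABL1 (0.0518) and wild-type replicate 2 without BCR-ABL1 (0.0961). For Spred1 adjusted p ran from 0.00663 to 0.199 over all alternatives.

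Among other genes, Il7r, the receptor gene for the pre-B growth factor interleukin 7, rose with SHP2 loss in these cells from 6.29 ± 0.754 to 11.9 ± 2.58 FPKM (SD, n = 4), a log2 change of 0.81 ± 0.12 (SE, limma adjusted p = 0.00249). Cdkn2d, a cyclin-dependent kinase inhibitor gene, rose from 10.3 ± 1.16 to 14.4 ± 0.918 FPKM. These were the 2 of 21 cell cycle inhibitors and FOXO targets that rose (5 adjusted over the list alone, and 4 over all genes with the replicate block), and the list had camera adjusted p = 0.0352, adjusted p = 0.275 with an estimated correlation, 0.0575 with the replicate block and 0.0622 after the added GC correction. That list call was lost on leaving out null replicate 0 without BCR-ABL1 (0.0533), null replicate 1 without BCR-ABL1 (0.0910), null replicate 2 without BCR-ABL1 (0.0639), wild-type replicate 1 without BCR-ABL1 (0.0848) and wild-type replicate 3 without BCR-ABL1 (0.0722). For the FOXO list adjusted p ran from 0.00465 to 0.275 with 1 choice changed at a time. The ETS factor gene Erg rose from 31.8 ± 4.43 to 53.5 ± 14.2 FPKM. The call was lost on leaving out null replicate 3 without BCR-ABL1 (0.0527), wild-type replicate 2 without BCR-ABL1 (0.0915) and wild-type replicate 3 without BCR-ABL1 (0.0861). For Erg adjusted p ran from 0.00913 to 0.167 over all alternatives. Il7r and Erg were the 2 of 21 early B lineage genes that rose (2 adjusted over the list alone, and 3 over all genes with the replicate block). That list did not pass in camera (adjusted p = 0.0839), but passed with median-ratio scaling (0.0463), the added GC correction (0.0425) and fry (0.00607), and its adjusted p ran from 0.00607 to 0.275 with 1 choice changed at a time.

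Ifi27l2a, an interferon-induced gene, rose from 14 ± 5.66 to 32.3 ± 7.76 FPKM (SD, n = 4). Its call was lost on leaving out null replicate 2 without BCR-ABL1 (0.0689) and wild-type replicate 2 without BCR-ABL1 (0.0661). For Ifi27l2a adjusted p ran from 0.00249 to 0.147 over all alternatives. Ifi27l2a was the 1 of 7 interferon response genes that rose (6 adjusted over the list alone, and 2 over all genes with the replicate block), and the list had camera adjusted p = 0.000462 and adjusted p = 0.275 with an estimated correlation (8.06e-05 to 0.275 with 1 choice changed at a time). Of the myeloid markers 5 of 5 had a positive change in the same comparison (mean log2 0.66, or 0.08 without null replicate 2), and the list did not pass (camera adjusted p = 0.436). MYC targets and ribosome biogenesis genes lay lower (36 of 40 members, 4 at an unadjusted p below 0.05, 0 passing singly in limma or adjusted over the list alone), with camera adjusted p = 2.01e-05 and adjusted p = 0.683 with an estimated correlation (2.24e-07 to 0.683 with 1 choice changed at a time). Their mean log2 change was -0.14, and -0.06 without null replicate 2, the library with the highest Lyz2. Glycolysis genes lay lower (15 of 17, 4 at an unadjusted p below 0.05, 0 passing singly in limma and 1 adjusted over the list alone), with camera adjusted p = 6.85e-05 and adjusted p = 0.683 with an estimated correlation (7.33e-08 to 0.683 with 1 choice changed at a time). Their mean log2 change was -0.41, and -0.19 without wild-type replicate 3. The hexokinase gene Hk2 averaged 11.2 ± 1.76 and 7.91 ± 0.724 FPKM (limma adjusted p = 0.0770, or 0.0413 with the replicate block). The mature or activated B cell list passed with the replicate block (camera adjusted p = 0.0241, against 0.531 without it, 0.0241 to 0.972 with 1 choice changed at a time).

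In the same comparison the protease gene Htra3 rose from 0.935 ± 0.424 to 6.13 ± 2.12 FPKM (SD, n = 4), Nlrp6, of the NOD-like receptor family, from 0.232 ± 0.120 to 2.25 ± 1.03 FPKM, and Hyi from 1.10 ± 0.388 to 3.52 ± 1.10 FPKM. Tmem119 fell from 10.6 ± 4.10 to 2.20 ± 1.47 FPKM, and the mast cell protease gene Cma1 fell from 2.10 to 3.98 FPKM to 0.0204 to 1.75 FPKM in single libraries. The class I histocompatibility gene H2-Q5, whose family members may share reads, is uncertain and read 2.61 ± 0.518 and 6.32 ± 1.56 FPKM (limma adjusted p = 0.00369). Mxd3 and Mxd4, which encode antagonists of MYC, averaged 9.31 ± 0.945 and 7.67 ± 1.14 FPKM in wild-type and 13.4 ± 0.716 and 12.1 ± 2.86 FPKM in null cells. They were the 2 of 11 MYC network genes that passed adjusted over the list alone, and neither passed over all genes (adjusted p = 0.0878 and 0.0890, or 0.0240 and 0.00877 with the replicate block). Myc had a log2 change of -0.25 ± 0.19 (SE) and did not pass.

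In all, 157 of 10210 genes changed without BCR-ABL1 (104 higher, 53 lower, 26 by at least 2-fold, or 50 with pseudocount 0.1), and 587 with the replicate block. Over all 10210 genes the groups did not overlap for 928 (9.09%), where chance gives 2.86%. The higher share was 66.2%, against 53.8% after quantile normalization and 51.4% after a GC correction chosen after the data were seen. It was larger with a mean of at least 5 FPKM, where 59 genes were higher, and with the replicate block (411 of 587 higher). The rank correlation of a library's deviations with GC content averaged 0.293 in this null group and -0.0501 in its wild-type group. With fits on the groups compared only, which leave fewer libraries and estimate the spread from these groups alone, 34 genes changed (11 by at least 2-fold), and among the genes given above for this comparison the calls lost were those of Dusp6 (0.109), Etv5 (0.109), Spred1 (0.199), Il7r (0.0505), Cdkn2d (0.0849), Erg (0.167), Ifi27l2a (0.147), Hyi (0.0595), Tmem119 (0.106) and Cma1 (0.119). The call of Spred1 was lost also with no filter (0.0634), array weights (0.0544) and the GC correction (0.0694). The count was 103 without null replicate 2, 80 without wild-type replicate 2 and 102 without wild-type replicate 3. Of the 152 called genes with a position other than Ptpn11, 24 lay within 20 Mb of Ptpn11 and 19 in the chromosome 17 window, and 109 lay elsewhere, H2-Q5 (chromosome 17, 35394126 to 35397800) among them. The macrophage gene Lyz2 read 403 FPKM in null replicate 2 and at most 34.3 FPKM in any other library, that value being from another null library without BCR-ABL1. In that library Dusp6 read 1.21 FPKM against 3.68 to 5.12 FPKM in the other null libraries, Il7r 15.7 against 9.88 to 11.6 FPKM and Ptpn11 2.87 against 6.02 to 7.43 FPKM.

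Genes that changed with SHP2 loss in both backgrounds included Hspb8, which changed by -2.80 ± 0.27 with and by -2.16 ± 0.27 without BCR-ABL1 (log2, SE), and Grina, which rose by 0.90 ± 0.14 and 1.14 ± 0.14. The call of Grina with BCR-ABL1 was lost after the added GC correction (adjusted p = 0.0523, 0.00025 to 0.0523 over all alternatives). In all 16 genes were higher in both comparisons (0.183 expected from independent lists) and 11 were lower in both (0.0727 expected), with 0 in opposite directions in limma. Of the 32 genes called with BCR-ABL1, 32 had the same sign without it. Of the 157 called without BCR-ABL1, 134 had the same sign with it. Their median absolute log2 change was 0.584 without BCR-ABL1 and 0.196 with it. They were selected by their change without it, which raises the first value. Among the genes called in both, 25 other than Ptpn11 had a position. Within 20 Mb of Ptpn11 lay 9 of them, and 10 lay in the chromosome 17 window. DNA linked to the Ptpn11 allele or strain background may thus raise the overlap, which the expectation from independent lists does not allow for. Across all 10210 genes, which are not independent replicates, the log2 changes correlated at r = 0.258 and rho = 0.244. The correlation was 0.377 without null replicate 0 and 0.136 without null replicate 3 of the cells with BCR-ABL1. These comparisons share no libraries.

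**Figure D2:**
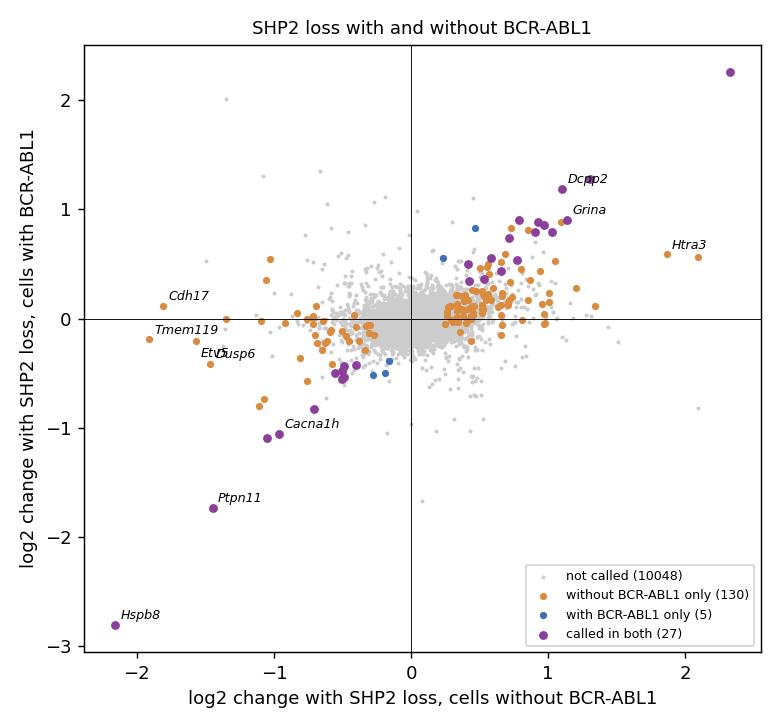
Log2 change with SHP2 loss in cells without BCR-ABL1 (x axis) against cells with BCR-ABL1 (y axis), log2(FPKM + 1) scale, 1 point per tested gene. Of the genes called in both, 16 lie higher in both and 11 lower in both, with Hspb8 and Ptpn11 among the lowest.

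**Figure D3:**
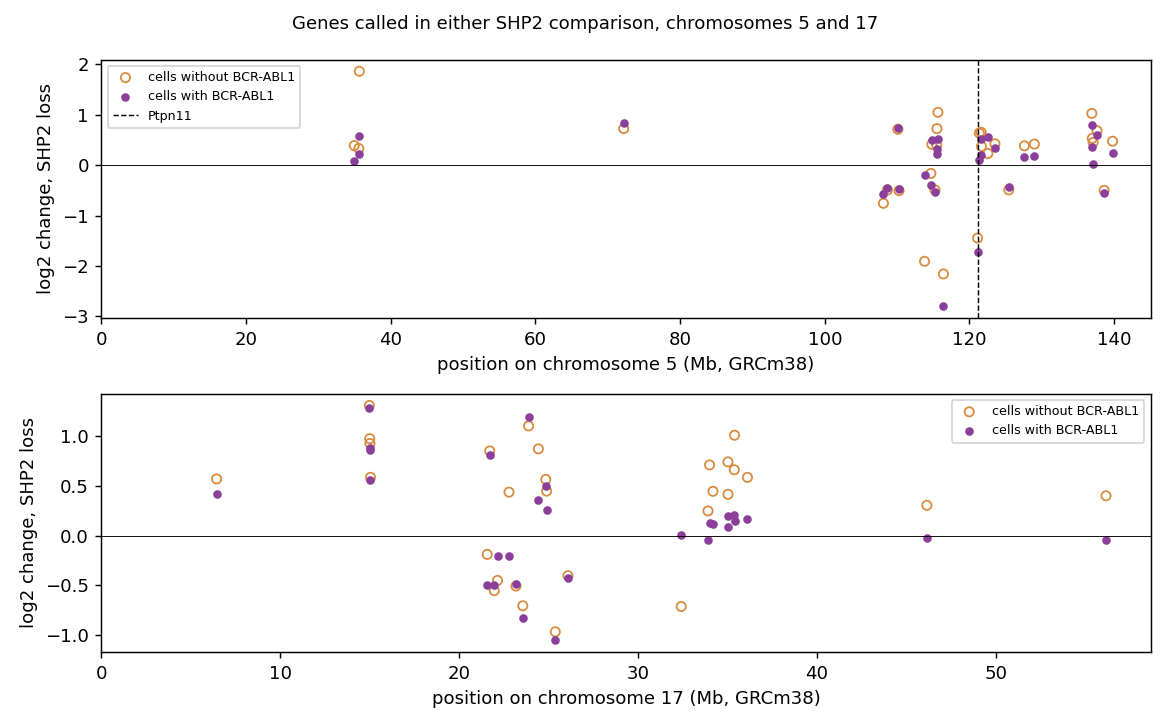
Log2 change with SHP2 loss of genes called in either SHP2 comparison, by position on chromosomes 5 and 17 (Mb, GRCm38), with open circles for cells without and filled circles for cells with BCR-ABL1. The dashed line marks Ptpn11, within 20 Mb of which 24 of the 152 positioned genes called without BCR-ABL1 lay.

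The third comparison asked whether the effect of SHP2 loss differed with BCR-ABL1. No gene passed over all genes (0 of 10210 in limma, smallest adjusted p = 0.0964, 591 genes at an unadjusted p below 0.05 against 510.5 expected by chance). On leaving out 1 library, 1 gene passed without null replicate 2 or wild-type replicate 1 lacking BCR-ABL1, or without wild-type replicate 2 carrying it. As a group the ERK list had a larger SHP2 effect without BCR-ABL1 on the log2(FPKM + 1) scale (camera adjusted p = 2.68e-05, or 0.00202 with pseudocount 0.1 as an added alternative, adjusted p = 0.119 with an estimated correlation, 3.27e-07 to 0.156 with 1 choice changed at a time). The difference was 1.05 ± 0.34 for Dusp6, 1.36 ± 0.36 for Etv5, 0.55 ± 0.14 for Spred2 and 0.67 ± 0.22 for Spred1 (log2, SE), the 4 of 9 genes that passed adjusted over the list alone. With pseudocount 0.1, which shrinks low genes less, these differences were 0.78, 1.73, 0.66 and 0.72, and Dusp6, Etv5 and Spred2 averaged below 1 FPKM with BCR-ABL1. Il7r differed by -0.82 ± 0.17 (limma adjusted p = 0.392), Ptpn11 by -0.28 ± 0.27, Abl1 by -0.18 ± 0.15, Bcr by -0.25 ± 0.17, Mxd3 by -0.46 ± 0.19, Mxd4 by -0.46 ± 0.23 and Myc by 0.10 ± 0.27, and none passed. Glycolysis genes differed as a group (16 of 17 with a positive difference, 8 at an unadjusted p below 0.05, 0 passing singly in limma and 1 adjusted over the list alone), with camera adjusted p = 1.49e-14 and adjusted p = 0.369 with an estimated correlation (3.38e-22 to 0.369 with 1 choice changed at a time). The 1 was Hk2, at 11.2 ± 1.76 and 7.91 ± 0.724 FPKM (SD, n = 4) in wild-type and null cells without BCR-ABL1 and 8.33 ± 0.838 and 9.97 ± 1.86 FPKM with it.

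The fourth comparison asked what BCR-ABL1 changes in cells with SHP2. Dusp6 fell from 11.3 ± 2.53 to 0.873 ± 0.172 FPKM (SD, n = 4), a log2 change of -2.70 ± 0.24 (SE, limma adjusted p = 1.32e-05), Etv5 from 5.95 ± 1.10 to 0.498 ± 0.147 FPKM, Spred2 from 2.03 ± 0.401 to 0.356 ± 0.144 FPKM and Spred1 from 14.8 ± 2.14 to 7.67 ± 0.598 FPKM. Of the 9 measured ERK response genes 7 fell (7 adjusted over the list alone), and the list passed in camera (adjusted p = 6.25e-11, adjusted p = 0.00662 with an estimated correlation, 3.51e-12 to 0.00662 with 1 choice changed at a time). Il7r rose from 6.29 ± 0.754 to 25.3 ± 3.09 FPKM, a log2 change of 1.85 ± 0.12 (SE, adjusted p = 1.18e-06).

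Early B lineage genes lay higher with BCR-ABL1 in SHP2 wild-type cells, 4 of 21 rising (5 adjusted over the list alone, while 1 fell). Besides Il7r they included Sox4, a transcription factor gene, from 18.8 ± 2.57 to 28.1 ± 1.66 FPKM (SD, n = 4), and Myb, a transcription factor gene of progenitor cells, from 90.2 ± 7.26 to 122 ± 7.18 FPKM. The call of Myb was lost with quantile normalization (adjusted p = 0.0557, 0.00233 to 0.0557 over all alternatives). The list had camera adjusted p = 0.0241 and adjusted p = 0.111 with an estimated correlation. That call was lost on leaving out wild-type replicate 3 without BCR-ABL1 (0.135) and wild-type replicate 1 with BCR-ABL1 (0.107). For early B lineage adjusted p ran from 7.25e-05 to 0.135 with 1 choice changed at a time. The surface receptor gene Cd72 rose from 22.3 ± 6.09 to 36.7 ± 2.86 FPKM, the 1 of 13 pre-BCR signalling genes to do so, while 1 fell (2 each adjusted over the list alone).

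In the same comparison, of 21 cell cycle inhibitors and FOXO targets 5 rose and 1 fell (8 and 1 adjusted over the list alone), with Cdkn2d rising from 10.3 ± 1.16 to 15.5 ± 0.830 FPKM (SD, n = 4), and the list did not pass in camera (adjusted p = 0.146) but did with fry (0.00152, range 0.00152 to 0.699 with 1 choice changed at a time). Zmat3, a p53 target, fell from 4.63 ± 1.31 to 1.30 ± 0.326 FPKM, and of 15 p53 targets 2 rose and 2 fell (3 and 2 adjusted over the list alone). In the BCL2 family Bok fell from 5.32 ± 1.12 to 2.43 ± 0.639 FPKM, and 1 of 13 rose and 1 fell, as many adjusted over the list alone. Of 19 SHP2 and RAS-ERK pathway members the scaffold gene Gab3 rose from 0.685 ± 0.0632 to 1.32 ± 0.239 FPKM and the RAS inhibitor gene Nf1 fell from 2.79 ± 0.560 to 1.55 ± 0.106 FPKM (2 rose and 1 fell adjusted over the list alone).

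Further genes that changed with BCR-ABL1 in SHP2 wild-type cells included the lymphoid surface gene Ly6d, which rose from 53.6 ± 16 to 205 ± 31.3 FPKM (SD, n = 4), Htra3, from 0.935 ± 0.424 to 6.07 ± 3.48 FPKM, Gas7, from 1.97 ± 0.379 to 7.33 ± 1.16 FPKM, and Nlrp6, from 0.232 ± 0.120 to 2.30 ± 0.628 FPKM. Cdh17, a cadherin gene, fell from 15.5 ± 6.49 to 0.679 ± 0.225 FPKM, Tmem119 from 10.6 ± 4.10 to 0.212 ± 0.0302 FPKM, the mast cell protease gene Cpa3 from 5.59 ± 1.83 to 0.546 ± 0.634 FPKM and Mgll, a lipase gene, from 5.46 ± 1.42 to 0.827 ± 0.129 FPKM. Cma1 read 2.10 to 3.98 FPKM without BCR-ABL1 and was listed at 0 in all 4 libraries with it. H2-Q9, whose family members may share reads, is uncertain and read 0.794 ± 0.271 and 4.88 ± 0.942 FPKM (limma adjusted p = 4.61e-05). Ptpn11, Mxd3, Mxd4 and Myc did not pass, with log2 changes of 0.02 ± 0.19, 0.42 ± 0.13, 0.51 ± 0.16 and -0.29 ± 0.19 (SE).

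Interferon response genes lay higher with BCR-ABL1 in SHP2 wild-type cells (7 of 7 members, 1 rising and 2 adjusted over the list alone), with camera adjusted p = 0.0183 and adjusted p = 0.699 with an estimated correlation. That call was lost on leaving out wild-type replicate 3 without BCR-ABL1 (0.0502). For interferon response adjusted p ran from 0.00207 to 0.699 with 1 choice changed at a time. MYC targets (30 of 40) and glycolysis genes (16 of 17) lay lower, with 1 and 1 members at an unadjusted p below 0.05 and 0 passing singly in limma or adjusted over the list alone. Their camera adjusted p values were 0.0241 and 0.00229, both with adjusted p = 0.982 with an estimated correlation. The MYC call was lost on leaving out wild-type replicate 1 without BCR-ABL1 (0.0830), wild-type replicate 3 without BCR-ABL1 (0.241), wild-type replicate 0 with BCR-ABL1 (0.0601) and wild-type replicate 1 with BCR-ABL1 (0.0927). Its mean log2 change was -0.069, and -0.030 without wild-type replicate 3 lacking BCR-ABL1. For MYC targets adjusted p ran from 0.00577 to 0.982 with 1 choice changed at a time. The glycolysis call was lost on leaving out wild-type replicate 3 without BCR-ABL1 (0.191). Its mean log2 change was -0.32, with -0.10 without that library and -0.49 without wild-type replicate 0 lacking BCR-ABL1 or wild-type replicate 2 carrying it. For glycolysis adjusted p ran from 2.41e-06 to 0.982 with 1 choice changed at a time. In all, 477 genes changed (301 higher, 176 lower, 61 by at least 2-fold, or 119 with pseudocount 0.1). Over all 10210 genes the groups did not overlap for 1194 (11.7%), where chance gives 2.86%. The higher share was 63.1%, and 51.9% after the added GC correction. The count was 235 and 296 without replicate 2 or 3 of the wild-type cells lacking BCR-ABL1, and 250, 305 and 306 without replicate 0, 2 or 3 of those carrying it.

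The fifth comparison asked what BCR-ABL1 changes in cells without SHP2. Dusp6 fell from 3.72 ± 1.79 to 0.406 ± 0.106 FPKM (SD, n = 4), a log2 change of -1.65 ± 0.24 (SE, limma adjusted p = 0.00429), and Spred2 from 0.854 ± 0.114 to 0.218 ± 0.0679 FPKM. The receptor tyrosine kinase gene Epha2 fell from 11.4 ± 2.10 to 6.32 ± 1.60 FPKM. Its call was lost on leaving out null replicate 0 with BCR-ABL1 (0.0546) and null replicate 2 with BCR-ABL1 (0.0658). For Epha2 adjusted p ran from 0.00339 to 0.103 over all alternatives. Dusp6, Spred2 and Epha2 were the 3 of 9 ERK response genes that fell (5 adjusted over the list alone, and 4 over all genes with the replicate block), with camera adjusted p = 9.02e-06 and adjusted p = 0.0750 with an estimated correlation (2.23e-07 to 0.0750 with 1 choice changed at a time). Il7r rose from 11.9 ± 2.58 to 25 ± 1.76 FPKM and Ccng2, an atypical cyclin gene, from 20.1 ± 4.03 to 37.8 ± 3.97 FPKM. Of the 21 cell cycle inhibitors and FOXO targets 3 rose and 1 fell (5 and 1 adjusted over the list alone, or over all genes with the replicate block), with camera adjusted p = 0.00219 and adjusted p = 0.129 with an estimated correlation. That call was lost on leaving out null replicate 1 with BCR-ABL1 (0.111). For the FOXO list adjusted p ran from 0.000199 to 0.129 with 1 choice changed at a time. Il7r was the 1 of 21 early B lineage genes that rose (2 rose and 1 fell adjusted over the list alone, and 2 rose over all genes with the replicate block; camera adjusted p = 0.0720).

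Among further genes in SHP2-null cells, the stress-response gene Nupr1 rose from 0.952 ± 0.511 to 5.0 ± 2.26 FPKM (SD, n = 4) and Khdrbs3, an RNA-binding protein gene, from 0.656 ± 0.253 to 2.25 ± 0.456 FPKM. Mgll fell from 4.60 ± 1.88 to 0.794 ± 0.165 FPKM and Mc1r, the melanocortin receptor gene, from 5.50 ± 2.32 to 1.21 ± 0.188 FPKM. Bcr fell from 10.04 ± 1.57 to 6.24 ± 0.855 FPKM (limma adjusted p = 0.0240). The call was lost on leaving out null replicate 3 without BCR-ABL1 (0.0760), null replicate 0 with BCR-ABL1 (0.0912) and null replicate 2 with BCR-ABL1 (0.105). For Bcr adjusted p ran from 0.00439 to 0.105 over all alternatives. Ptpn11, Abl1, Mxd3, Mxd4 and Myc did not pass, with log2 changes of -0.26 ± 0.19, -0.27 ± 0.10, -0.05 ± 0.13, 0.06 ± 0.16 and -0.19 ± 0.19 (SE).

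Glycolysis genes lay higher with BCR-ABL1 in SHP2-null cells (17 of 17, camera adjusted p = 2.12e-05, adjusted p = 0.788 with an estimated correlation, 3.24e-09 to 0.788 with 1 choice changed at a time). Cholesterol synthesis lay higher (14 of 18, adjusted p = 0.0408, or 0.0803 with the replicate block), and MYC targets (32 of 40) and E2F targets (24 of 29) lay lower (camera adjusted p = 0.0145 and 0.0341), all with adjusted p = 0.864 with an estimated correlation. In these 4 lists 0 members passed singly in limma or adjusted over the list alone, and 3, 2, 6 and 2 were at an unadjusted p below 0.05. With the replicate block 1 glycolysis gene rose and 2 MYC targets fell. The cholesterol call was lost on leaving out null replicate 3 without BCR-ABL1 (0.908), null replicate 0 with BCR-ABL1 (0.0763) and null replicate 1 with BCR-ABL1 (0.385). For cholesterol synthesis adjusted p ran from 0.000471 to 0.908 with 1 choice changed at a time. The MYC call was lost on leaving out null replicate 0 without BCR-ABL1 (0.0693), null replicate 3 without BCR-ABL1 (0.402) and null replicate 1 with BCR-ABL1 (0.208). For MYC targets adjusted p ran from 3.97e-06 to 0.864 with 1 choice changed at a time. The E2F call was lost on leaving out null replicate 0 without BCR-ABL1 (0.0719), null replicate 3 without BCR-ABL1 (0.312) and null replicate 1 with BCR-ABL1 (0.413). For E2F targets adjusted p ran from 0.00103 to 0.864 with 1 choice changed at a time. Without null replicate 2 lacking BCR-ABL1, the library with the highest Lyz2, the mean log2 change was -0.18 for MYC targets, against -0.10, and 0.26 for cholesterol synthesis, against 0.16. Without null replicate 3 lacking BCR-ABL1 it was -0.043 for MYC targets, 0.0045 for cholesterol synthesis and -0.049 for E2F targets, against -0.082, and without null replicate 1 carrying BCR-ABL1 it was -0.049 for E2F targets. For glycolysis it was 0.30 without null replicate 2 carrying BCR-ABL1, against 0.46. Myeloid markers had a mean log2 change of -0.77 in this comparison (3 of 5 negative and 3 at an unadjusted p below 0.05), and -0.19 without null replicate 2 lacking BCR-ABL1. Of these markers 0 passed over all genes in limma, while 1 fell adjusted over the list alone and 1 with the replicate block, and the list did not pass (camera adjusted p = 0.258). Replication histones passed with the replicate block (adjusted p = 0.0127, against 0.0720, 0.00152 to 0.876 with 1 choice changed at a time), and SRC family kinases after the added GC correction (0.0262, against 0.0730, 0.0262 to 0.465).

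In all, 129 genes changed with BCR-ABL1 in SHP2-null cells (59 higher, 70 lower, 17 by at least 2-fold), and 538 with the replicate block (32 by at least 2-fold). With pseudocount 0.1, 45 changed by at least 2-fold. With fits on the groups compared only, which leave fewer libraries and estimate the spread from these groups alone, 30 changed (7 by at least 2-fold), and among the genes given above for this comparison the calls lost were those of Dusp6 (0.0543), Epha2 (0.103), Nupr1 (0.0543) and Bcr (0.0763). Over all 10210 genes the groups did not overlap for 722 (7.07%), where chance gives 2.86%. The higher share was 45.7%, and 56.3% after the added GC correction. The count was 70 and 61 without null replicate 0 or 3 lacking BCR-ABL1, and 55 and 49 without null replicate 0 or 2 carrying it. By at least 2-fold there were 5 without null replicate 3 lacking BCR-ABL1, and 8 and 6 without null replicate 0 or 2 carrying it. Without the library with the highest Lyz2 it was 176. Il7r rose, and Dusp6, Spred2 and Mgll fell, with and without SHP2. In all 49 genes were higher in both BCR-ABL1 comparisons (1.74 expected from independent lists) and 48 lower in both (1.21 expected), and 464 of the 477 genes called with SHP2 had the same sign without it. The log2 changes correlated across genes, which are not independent replicates, at r = 0.547, and these comparisons share no libraries.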

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

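The tests of the myeloid pattern in this part were chosen after the result was seen, with 20 macrophage genes for one of them written down before their values were read, while the list tests of the interaction and the search for single libraries far from their group were planned, though the genes searched were chosen after their values were seen.

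In 26 of 366 groups of 4 libraries, over 93 genes, 1 library stood far from the other 3 (18.3 expected by chance). In SHP2 wild-type cells without BCR-ABL1 these were replicate 0 for Mxd4 (5.97 against 8.05 to 8.40 FPKM), Tmem254b (20.6 against 15.9 to 16.7) and Grtp1 (0.368 against 1.05 to 1.17), replicate 1 for Ccr2 (0.397 against 0.163 to 0.200), H2-Q9 (1.20 against 0.623 to 0.680), Igj (28.2 against 2.23 to 5.09) and Tlr7 (0.856 against 0.748 to 0.758), replicate 2 for Irs2 (2.10 against 1.16 to 1.32) and Sulf2 (4.25 against 2.05 to 2.18), and replicate 3 for Zfp948 (0.887 against 0.661 to 0.696). In SHP2-null cells without BCR-ABL1 replicate 2 stood apart for Lyz2 (403 against 6.08 to 34.3), Ccdc64 (7.18 against 2.43 to 3.06), Stxbp6 (5.07 against 1.27 to 1.83) and Grtp1 (0.0503 against 1.64 to 1.74), and replicate 3 for Abl1 (15.8 against 18.4 to 18.8), Irs2 (1.76 against 1.21 to 1.28), Gas7 (6.97 against 4.06 to 4.32) and Sit1 (29.4 against 15 to 15.6). With BCR-ABL1, wild-type replicate 2 stood apart for Zfp213 (5.97 against 4.31 to 4.46) and Slc2a1 (10.8 against 5.0 to 5.93) and replicate 3 for Ly6d (158 against 217 to 226) and Mxi1 (2.49 against 2.73 to 2.78). Null replicate 1 stood apart for Bok (2.52 against 2.31 to 2.34), replicate 2 for Tmem119 (0.0965 against 0.0492 to 0.0568) and Kdm5b (4.54 against 2.67 to 2.77), and replicate 3 for Cacna1h (0.002353, the others being listed at 0).

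In 5 gene lists the SHP2 effect differed between cells with and without BCR-ABL1 by the interaction test of limma's camera with the preset correlation. The mean difference, with minus without BCR-ABL1, was 0.38 for ERK pathway response (log2, 6 of 9 members positive), 0.78 for glycolysis (16 of 17 positive), 0.15 for cholesterol synthesis (15 of 18 positive), -0.15 for DNA replication and E2F targets (27 of 29 negative) and -0.38 for interferon response (7 of 7 negative). The adjusted p values were 2.68e-05, 1.49e-14, 0.00329, 0.000199 and 0.0254, and with an estimated correlation adjusted p = 0.119, 0.369, 0.715, 0.466 and 0.466. Adjusted over the list alone, 4, 1, 0, 1 and 0 members passed, against 0 over all genes in limma (4, 8, 1, 4 and 1 at an unadjusted p below 0.05). For E2F targets adjusted p ran from 4.78e-07 to 0.466 with 1 choice changed at a time. The interferon call was lost on leaving out null replicate 2 without BCR-ABL1 (0.269), null replicate 3 with BCR-ABL1 (0.0536) and wild-type replicate 3 with BCR-ABL1 (0.0774). For interferon response adjusted p ran from 0.00349 to 0.466 with 1 choice changed at a time, and the mean difference was -0.21 without that null replicate 2. The cholesterol call was lost on leaving out null replicate 3 without BCR-ABL1 (0.486), wild-type replicate 0 without BCR-ABL1 (0.106), wild-type replicate 1 without BCR-ABL1 (0.0917) and wild-type replicate 0 with BCR-ABL1 (0.294). For cholesterol synthesis adjusted p ran from 1.07e-06 to 0.715 with 1 choice changed at a time. Its mean difference was 0.00038, 0.062, 0.088 and 0.038 without these libraries, and 0.26, 0.29 and 0.26 without null replicate 2 or wild-type replicate 2 lacking BCR-ABL1 or wild-type replicate 1 carrying it. Myeloid markers differed by -0.99 on average (5 of 5 negative, camera adjusted p = 0.134, or 0.0488 after the added GC correction, 0.00996 to 0.715 with 1 choice changed at a time), and by -0.41 without null replicate 2 lacking BCR-ABL1.

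Myeloid genes, of which 5 passed the filter on expression, stood out in null replicate 2 of the cells without BCR-ABL1. Lyz2 read 403 FPKM there and 34.3 in the next library, Cd68 12.4 and 2.36, Fcgr3 9.10 and 1.39 and Csf1r, outside the rule for named genes and chosen after its values were seen, 3.57 and 0.543, each next library being another of the same group, while the neutrophil gene S100a8 was not highest there (3.07 against 9.34 FPKM in another library). RNA of macrophages in that library is a candidate explanation, since 15 of 19 macrophage genes outside the fixed list were highest there, against 3.57 on average in 10000 random lists matched on mean FPKM (permutation p = 1e-04, the smallest they can give), and such genes vary together. For an effect of SHP2 loss itself, 0 of the 5 markers had a median in the other 3 libraries of the group above all 4 wild-type libraries, but Ptpn11 was lowest in this library (2.87 against 6.02 to 7.43 FPKM), so a stronger effect there cannot be told apart from macrophage RNA. Without that library the counts of changed genes were 32 and 103 for SHP2 loss with and without BCR-ABL1, 1 for the interaction, and 636 and 176 for BCR-ABL1 with and without SHP2.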

How the results depend on the processing

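The GC corrections, pseudocount 0.1 for the list tests, the counts outside 2 genome windows and the omission of null replicate 2 without BCR-ABL1 from comparisons it is not part of were chosen after the data were seen. No called result changed sign (0 cases). Counts of changed genes are given in the order SHP2 loss with BCR-ABL1, SHP2 loss without it, BCR-ABL1 with SHP2 and BCR-ABL1 without SHP2, where they were 32, 157, 477 and 129 (interaction 0). With a mean of at least 5 FPKM, which tests fewer genes, they were 11, 70, 186 and 33. Without a filter, which tests more genes, the interaction count was 3. With fits on the groups compared only, which leave fewer libraries in each comparison, SHP2 loss without BCR-ABL1 gave 34 and BCR-ABL1 without SHP2 gave 30. Both include the null group without BCR-ABL1. For SHP2 loss with BCR-ABL1 and BCR-ABL1 with SHP2, the counts of higher genes and of 2-fold changes stayed within 1.5 times. Whether the shared estimate of the spread is too small for that null group was not tested. Array weights gave 644, 837 and 1861 for the last 3 and 2 for the interaction, and the cause was not tested. The replicate block gave 587, 1231 and 538 for the last 3, and included all 157, 477 and 129 genes called without it. Of the genes of the naming rule it gave calls to 0, 17 and 13 more in the 3 comparisons whose same-number pairs all correlated above 0.1 (SHP2 loss with and without BCR-ABL1, and BCR-ABL1 without SHP2), among them Hk2, Mxd3 and Mxd4, and took away 0. It changed no other list call there than those given in the report. For BCR-ABL1 with SHP2 and for the interaction not every pair of the same number correlated above 0.1 (lowest 0.0549). The interaction count was 0 with the block, with 1259 genes at an unadjusted p below 0.05 against 591. Of 48 best matches between groups 32 had the same number, a hint from the data. Replicates 0 and 1 matched their own number in every case, while replicates 2 and 3 mostly did not. Wild-type replicate 2 with BCR-ABL1 matched replicate 3 best in null cells with BCR-ABL1 (0.822) and in wild-type and null cells without it (0.725 and 0.630). Wild-type replicate 3 with BCR-ABL1 matched replicate 2 best in the first 2 of these groups (0.478 and 0.457) and replicate 3 in the last (0.484). Whether the number pairs these libraries is thus uncertain. With the block the interaction call of interferon response was lost (camera adjusted p = 0.0573) and replication histones gained one (0.0120, against 0.0963, as with median-ratio scaling, 0.0375, and the GC correction, 0.0488). With the block and an estimated correlation together 0 lists passed (smallest adjusted p = 0.0574), the ERK list of BCR-ABL1 with SHP2 among those lost (0.0733). The block with a GC correction gave 62, 601, 1686 and 589, and the cause was not tested. Outside the windows on chromosomes 5 and 17, which leaves fewer genes, SHP2 loss with BCR-ABL1 gave 9, of which 1 has no position. List calls were 27, with 2 under an estimated correlation and 11 under fry, which ended 19 and added 3, and 27 with pseudocount 0.1. Leaving out 1 library gave 20 to 32, 80 to 164, 235 to 636 and 49 to 176 genes, 0 to 1 for the interaction, and a correlation of SHP2 effects of 0.136 to 0.377. Pseudocount 0.1, median-ratio scaling, quantile normalization and a robust prior variance left every count of all changed genes within 1.5 times, while pseudocount 0.1, which shrinks low genes less, gave 16, 50, 119 and 45 genes changed by at least 2-fold, against 7, 26, 61 and 17. Of the values of named genes with 1 library left out, 211 lost their call, 22 gained one and 4721 did neither, and of those of gene lists 35, 38 and 977. Unknown depth limits genes of low FPKM, those near or below 1 FPKM included.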

Other observations

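The tests of explanations and the counts of splits in this part were chosen after the result was seen, while the list tests were planned.

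Beyond the fixed lists, Rnase12, of the ribonuclease family, fell from 11.6 ± 2.72 to 2.04 ± 0.539 FPKM (SD, n = 4) with BCR-ABL1 in SHP2 wild-type cells (limma adjusted p = 1.32e-05). With BCR-ABL1 in SHP2-null cells the histone demethylase gene Kdm5b rose from 1.03 ± 0.234 to 3.17 ± 0.915 FPKM and Tlr7, a sensor gene for RNA, from 0.724 ± 0.298 to 2.21 ± 0.619 FPKM, a call lost with fits on the groups compared only (adjusted p = 0.0664, 0.00180 to 0.0664 over all alternatives).

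Several lists passed camera in none of the 5 comparisons with the preset correlation before any alternative. Their smallest adjusted p values were 0.0972 for mitosis (22 genes), 0.285 for the MYC MAX MXD network (11), 0.130 for STAT5 targets (14), 0.0730 for SRC family kinases (9), 0.506 for SHP2 and RAS-ERK pathway members (19), 0.210 for pre-BCR signalling (13), 0.409 for mature or activated B cell (7), 0.769 for p53 targets (15), 0.397 for the BCL2 family (13), 0.0720 for replication histones (14), 0.134 for myeloid markers (5) and 0.437 for T and NK cell markers (3). T and NK cell markers passed with fry for BCR-ABL1 with SHP2 (0.0288, range 0.0288 to 0.880 with 1 choice changed at a time). After the added GC correction mitosis passed in the interaction (0.0431, range 0.0234 to 0.944) and for BCR-ABL1 with SHP2 (0.0481, range 0.0172 to 0.982). With the replicate block 3 STAT5 targets rose and 1 fell, and 3 pre-BCR genes rose, in SHP2 loss without BCR-ABL1. In the MYC network Mxi1 passed adjusted over the list alone in SHP2 loss with BCR-ABL1 (0 over all genes in limma, 1 at an unadjusted p below 0.05).

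Other splits of the libraries bear on the counts of changed genes. For BCR-ABL1 with SHP2, 1 of 35 splits of the 8 libraries, the real one, gave as many as 477 genes (highest other 0). That share is under 0.05, but it does not exclude chance. Other splits leave the real difference inside their groups, which widens the spread and lowers their counts. All 35 splits were used because only 3 of 4 same-number pairs correlated above 0.1. With the 8 splits that part all same-number pairs, as used below, the share could not fall under 0.05. For SHP2 loss with BCR-ABL1 (real 32, highest other 0), SHP2 loss without it (157 and 0) and BCR-ABL1 without SHP2 (129 and 1), the 8 splits that part all same-number pairs, of which 1 reached the real count in each, were too few for a share under 0.05. In these 3 the split of replicates 0 and 1 of both groups against replicates 2 and 3 gave 85, 189 and 283 genes. The other splits that kept all same-number libraries together gave 0 or 1. This points to a difference between replicates 0 and 1 and replicates 2 and 3, rather than to a structure by each single number. With the replicate block the real counts were 48, 587 and 538. For the interaction the real count was 0, which 100 of 100 drawn reassignments reached by necessity (highest other 125), so this count says nothing about chance.

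Genes called in both SHP2 comparisons lay together on chromosomes 5 and 17. Of 25 with a position other than Ptpn11, 9 lay within 20 Mb of Ptpn11 (0.755 expected). Flanking DNA carried with the Ptpn11 allele may explain this result. The permutation p was 1e-04, the smallest that 10000 permutations can give. The busiest 20 Mb outside chromosome 5 held 10 (2.07 expected; permutation p = 1e-04, again the smallest they can give), in line with strain background elsewhere in the genome. Of the other 6, 3 lay on chromosome 9 and 1 each on chromosomes 10, 15 and X. The design ties these 6 to SHP2 status and to any linked DNA alike. Loss of SHP2 itself and linked DNA therefore cannot be told apart for them. Of the genes called with BCR-ABL1 in SHP2 wild-type cells, 8 of 473 lay near Ptpn11 (14.3 expected, permutation p = 0.977). Their busiest 20 Mb outside chromosome 5 held 23 (16.9 expected, 95th percentile 22, permutation p = 0.0269). For BCR-ABL1 in SHP2-null cells the busiest held 6 (6.38 expected, permutation p = 0.772). Passing that test was thus not particular to the SHP2 comparisons, though the excess over expectation was larger for the genes called in both of these.

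SHP2 loss without BCR-ABL1 moved genes the way BCR-ABL1 did in SHP2 wild-type cells (r = 0.630 across genes, which are not independent replicates). In all 54 were higher in both and 31 lower in both (3.07 and 0.914 expected from independent lists). However, both comparisons use the same 4 control libraries. Simulated unchanged groups that shared controls, drawn from the deviations of all 16 libraries, gave r = 0.470 on average (-0.432 to 0.949). The correlation did not need the library with macrophage genes, since r was 0.647 without it. The shared controls, which can hold r up by themselves, stayed in that fit, so it does not rule out a part for that library. Without that library 65 genes were called in both comparisons in the same direction. With the controls split 6 ways, so that the comparisons shared none, r was 0.111 to 0.649 (mean 0.366). Of 100 simulations 7 reached that mean (95th percentile 0.455). The simulated groups mixed replicate numbers at random, while each real group held 1 of each number, so their spread need not match. The test by split controls therefore does not decide whether shared controls explain the correlation. The bound for that test was set anew after its value was seen. The covariance was 0.0333 against 0.0134 simulated (highest 0.0779), and the difference of 0.0200 leaves an effect of both conditions on the same genes open.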
